A study of Mus musculus with 3 samples.

How the data were processed

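DNase-seq maps stretches of chromatin that the nuclease DNase I can cut, which are mostly promoters, enhancers and other regulatory elements. It was carried out here on Müller cells, the radial glia of the vertebrate retina, taken as primary cells from 12 day old mice of the B6NCrl strain with both sexes pooled, per the labels. The series holds 1 group of 3 biological replicates, numbered 1, 2 and 3 in the labels. Each replicate has its own biosample label and all share the same donor label, so standard deviations measure the spread between these samples, part of which may be technical. The p-values below are over genes or sites and do not measure that spread. The labels point to a nuclei and DNase protocol written for cultured cells. They name no sort, no time in culture and no treatment.

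For each replicate the authors deposited a list of peaks and a list of hotspots, both with coordinates on the mouse build mm10. Per the deposited descriptions, each list was derived from the filtered alignments of that library alone plus 1 further file, so replicates were not pooled. The aligner, the peak caller, their versions and the read filters are not given in the sources used here. Peaks are 150 bp wide, apart from a few shorter ones, and the value that goes with each peak in the deposited files is a score, a whole number between 1 and 150. What the score counts is not stated. Its highest value equals the peak width, so it can saturate at the strongest sites, and no test here compares its values between replicates. It was used to rank or filter peaks within a replicate and to correlate replicates, and scores are given per replicate as a description. Hotspots are wider regions of variable length, and their deposited value is a −log10 q, which runs from 1.30 to a cap of 100; their score column is about 10 times that value. Every peak overlaps a hotspot of its replicate. Read depth is unknown, since no counts come with these lists; the number of peaks found in a library moves with its depth and its signal to noise, so peak numbers were compared with that in mind and every overlap was also computed with the same number of peaks from each replicate.

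Peaks that repeated another peak's position were removed, 21 from replicate 1, 20 from replicate 2 and 23 from replicate 3. Peaks of all replicates were merged where they overlapped by at least 1 bp. A merged region with a peak from all 3 replicates is called a reproducible site. Chance overlap was measured with 100 random placements of every replicate's peaks on their own chromosome outside assembly gaps, and with 20 placements for each alternative. Peak strength was compared between replicates with Spearman's rho and Pearson's r of log10 score, across regions, which are not independent replicates.

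Sites on autosomes and X were set against 21646 protein-coding genes, 1 per symbol, of the GENCODE M21 annotation, whose chromosome lengths are those of mm10. A promoter site lies within 1 kb of an annotated protein-coding start site. A gene is called open, or its promoter open, where a reproducible site lies within 1 kb of any of its start sites; the term describes DNase accessibility and not transcription. Other sites are distal, and were given to the gene with the nearest start site within 100 kb, a rule of distance that does not show which gene a site regulates. Exon, intron and intergenic classes were read at the centre of the site, and their shares were compared with 20 random placements of the reproducible sites.

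A total of 24 gene lists with 476 genes and 28 consensus motifs were fixed before the data were examined, together with the tests and the alternatives. The lists cover Müller glia, retinal progenitors, neurogenic factors, rods, cones, bipolar cells, amacrine and horizontal cells, retinal ganglion cells, pigment epithelium, astrocytes, oligodendrocytes, endothelium, pericytes and mural cells, microglia and macrophages, mesenchymal and matrix genes, gliosis and stress genes, the Notch pathway, the YAP and TEAD pathway, the cell cycle, housekeeping genes, liver, striated muscle, germline and Hox genes. Every list gene was found by symbol. Some genes sit in more than 1 list. Open promoters of a list were compared with those of all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. Distal sites per gene were compared with 100000 random lists of the same size, matched in quintiles on the length of genome that would be given to each gene; this two-sided permutation test cannot give a p under 2e-05. Motifs were searched on both strands in 150 bp round each site's centre, and the share of sites with a match was compared with windows of the same width 1 kb to either side that overlap no peak, by Fisher's exact test, two-sided, adjusted over the 28 motifs. A consensus match is not evidence that a factor is bound, and members of a factor family share a consensus. Sites are not replicates, so each motif ratio is also given as the mean and SD of the ratios of the 3 replicates' own peaks.

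Genes named in the text were set by a rule: genes always considered (among them Rlbp1, Glul, Sox9, Sox2, Lhx2, Pax6, Hes1, Nrl, Crx, Otx2 and Gfap); in each retinal cell list the 3 genes with most reproducible distal sites and the first 2 in alphabetical order with no promoter peak in any replicate, and 2 and 1 in each other list; the 10 genes with most reproducible distal sites; and the nearest genes of the 10 distal sites whose worst rank of strength over the replicates is best. The text names fewer than these, and states where genes were chosen after their values were seen.

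Alternatives left out each replicate, took the same number of peaks per replicate, used hotspots, the strongest 50% of peaks, sites in at least 2 replicates, a 50% overlap, promoter windows of 500 bp and 2500 bp, distance limits of 50 kb and 500 kb, medians, random lists matched on the CpG content of promoters, motif windows matched on GC content in bins of 5%, and shuffled consensus sequences. Each replicate's own peaks were added as a setting after the data were seen. Tests on sites and promoters found in some replicates and not in others were also chosen then, with 4 further lists: a second list of macrophage genes (21 of them in the annotation) and lists of T cell (14), B cell (10) and erythroid genes (10). No test compares groups, since there is only 1, and a rule for single outlying samples needs more than 3.

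The procedures were first tested on simulated data. Merging recovered all 20000 regions that 3 simulated replicates shared. Of random lists, 3.50% passed an unadjusted 0.05 in the promoter test and 5% in the distal test, and 90% of lists with 2 times the distal sites passed. A planted AP-1 motif was found in 31.3% of simulated sites, where 31.2% were expected to hold it by planting or by chance. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and samtools 1.23.1 for the genome sequence.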

Results

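Chromatin accessibility was mapped by DNase-seq in primary Müller cells from mouse retina at postnatal day 12, in 3 biological replicates of a single group. The labels state no question beyond profiling this cell type, so the account below asks which sites are shared by the replicates, which cell types and pathways their genes belong to, and which sequence motifs they hold. Replicate 1 had 300269 peaks covering 44.6 Mb, replicate 2 had 281185 peaks covering 41.7 Mb and replicate 3 had 184544 peaks covering 27.3 Mb. The mean was 255333 ± 62043 peaks (SD, n = 3). Hotspots numbered 269267, 259229 and 161437 in replicates 1, 2 and 3. Read depth is unknown, so the lower numbers of replicate 3 cannot be set against its depth.

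The replicates shared a large common set of accessible sites, and replicates 1 and 2 resembled each other more than either resembled replicate 3. The peaks merged into 352310 regions, of which 145369 (41.3%) had a peak in all 3 replicates. When the peaks were placed at random the share was 0.0448% on average and 0.0497% at most in 100 placements. Without replicate 1, 2 or 3 the regions shared by the other replicates were 49.2%, 47.8% and 70.5%. A further 89306 regions were found in replicates 1 and 2 without replicate 3, compared with 7962 in replicates 1 and 3 and 4654 in replicates 2 and 3. With the same number of peaks taken from each replicate, 123678 of 242947 regions (50.9%) were in all 3, and 39391 were in replicates 1 and 2 alone. The order of regions found in a single replicate depended on the number of peaks taken. With all peaks replicates 1, 2 and 3 alone held 50387, 34609 and 20023, and with the same number of peaks 12550, 12732 and 41667.

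**Figure D1:**
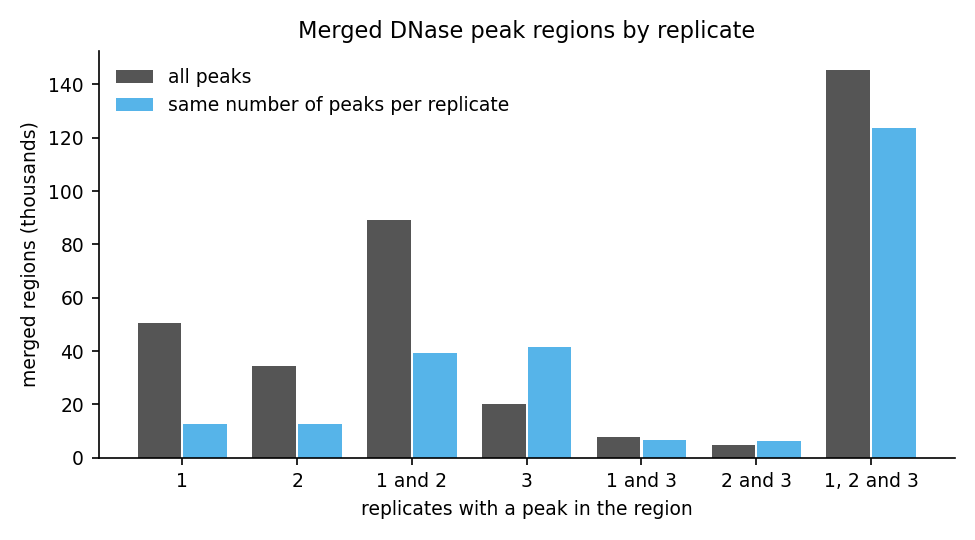
Number of merged peak regions (y axis) by the replicates in which they had a peak (x axis), for all peaks (dark bars) and for the same number of peaks per replicate (light bars). The bars for all 3 replicates are the highest, at 145369 and 123678 regions.

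Peak strength was also most alike between replicates 1 and 2. Across regions found in both replicates of a pair, Spearman's rho of the deposited score was 0.948 between replicates 1 and 2, 0.784 between 1 and 3, and 0.789 between 2 and 3. Pearson's r of log10 score was 0.940, 0.767 and 0.780. These values are across regions, which are not independent replicates.

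Accessible sites were strongly concentrated at promoters, although most lay in introns or between genes. Of the 145262 reproducible sites on autosomes and X, 24974 (17.2%) lay within 1 kb of a protein-coding start site, against 2.82% when the sites were placed at random. Introns held 41.5% (41.8% at random), intergenic sequence 36.4% (51% at random) and exons 4.89% (4.37% at random). The promoter share of the replicates' own peaks was 13.2%, 13.5% and 17.6% in replicates 1, 2 and 3 (mean 14.7% ± 2.46, SD, n = 3). A reproducible site lay at the promoter of 14524 of the 21646 genes (67.1%). With 2500 bp in place of 1 kb the share of promoter sites was 21.7%, and among the strongest 50% of peaks it was 25.4%.

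The promoters of Müller glia genes were open throughout. All 32 genes of the list had a reproducible promoter site, and each of the replicates alone also had a peak at all 32. The share among all other genes was 67.0% (Fisher's exact test, adjusted p = 2.61e-05). The list holds genes of glutamate and retinoid handling, water and potassium channels, and transcription factors that mark these cells. Random lists with the same promoter CpG content had 24.0 open genes on average (adjusted p = 0.00016 in that permutation test).

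Among the named Müller genes, Rlbp1, which encodes the retinaldehyde-binding protein of the visual cycle, lies on chromosome 7 from 79374870 to 79387048 (mm10, minus strand). Its promoter site at 79386856 to 79387045 had scores of 107, 93 and 109 in replicates 1, 2 and 3. Glul, which encodes glutamine synthetase, lies on chromosome 1 from 153899944 to 153909723. The promoter site nearest to its start, at 153899796 to 153899945, scored 142, 141 and 131. Sox9, a transcription factor of glia and their precursors, lies on chromosome 11 from 112782224 to 112787760, and its promoter site at 112782056 to 112782245 scored 146, 143 and 138. At Aqp4, the water channel of glial endfeet, the strongest promoter peak scored 108, 104 and 74. The deposited score stops at 150, so it may compress differences among sites that score near that value, which was not tested.

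Of the 24 genes of retinal progenitors 19 had a reproducible promoter site (79.2%), a share that did not differ from that of other genes by Fisher's exact test (adjusted p = 0.392). Random lists with the same promoter CpG had 21.2 open genes on average (permutation test, adjusted p = 0.367). Open members included Sox2 on chromosome 3, Pax6 and Lhx2 on chromosome 2, and Hes1 on chromosome 16, transcription factors that progenitors and Müller glia have in common. Lin28b, which encodes an RNA-binding protein of early development, had no promoter peak in any replicate. The Otx2 promoter, of a factor needed for photoreceptor and bipolar cell fate, had no peak in replicate 1 and peaks of 21 and 41 in replicates 2 and 3. With the peaks of replicate 3 alone, 23 of 24 progenitor genes had a promoter peak, and that share passed the exact test (adjusted p = 0.00737). Of the 17 neurogenic factors 12 were open (70.6%, exact test, adjusted p = 1; 14.3 in CpG-matched random lists), among them Prdm1, while Neurod6 and Ptf1a had no promoter peak.

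Rod photoreceptor promoters were mostly closed. Only 5 of 24 rod genes had a reproducible promoter site (20.8%, Fisher's exact test, adjusted p = 2.61e-05), and every replicate alone gave the same count of 5. Nrl and Crx, transcription factors of photoreceptor identity, had no promoter peak in any replicate. The open members, named here after their values were seen, were Aipl1, Cnga1, Cngb1, Reep6 and Rom1, and at Rom1 every site lay nearer to the start site of another gene. Random lists with the same promoter CpG content had 10.9 open genes on average (permutation test, adjusted p = 0.0307). Cone genes were open in 6 of 14 cases (42.9%, exact test, adjusted p = 0.142). Thrb, the thyroid hormone receptor used in cone specification, was open, and Arr3 and Gnat2, which encode cone phototransduction proteins, had no promoter peak.

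Lists of the other retinal neurons had open promoters at about the share of genes in general. They were open for 15 of 22 bipolar genes (68.2%) and 15 of 22 amacrine and horizontal cell genes (68.2%), both with an adjusted p = 1 in Fisher's exact test, and for 15 of 19 retinal ganglion cell genes (78.9%, adjusted p = 0.424). Irx5 and Irx6, homeobox genes of bipolar subtypes, Prox1, a factor of horizontal and amacrine cells, and Rbpms, a marker of ganglion cells, were open. Cabp5, Chat and Sncg, markers of mature bipolar, cholinergic amacrine and ganglion cells, had no promoter peak in any replicate. Random lists matched on promoter CpG had 13.9, 18 and 14.9 open genes on average for the same lists. In the pigment epithelium list 12 of 18 promoters were open (66.7%, exact test, adjusted p = 1), with Mitf open and Best1 without a promoter peak.

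**Figure D2:**
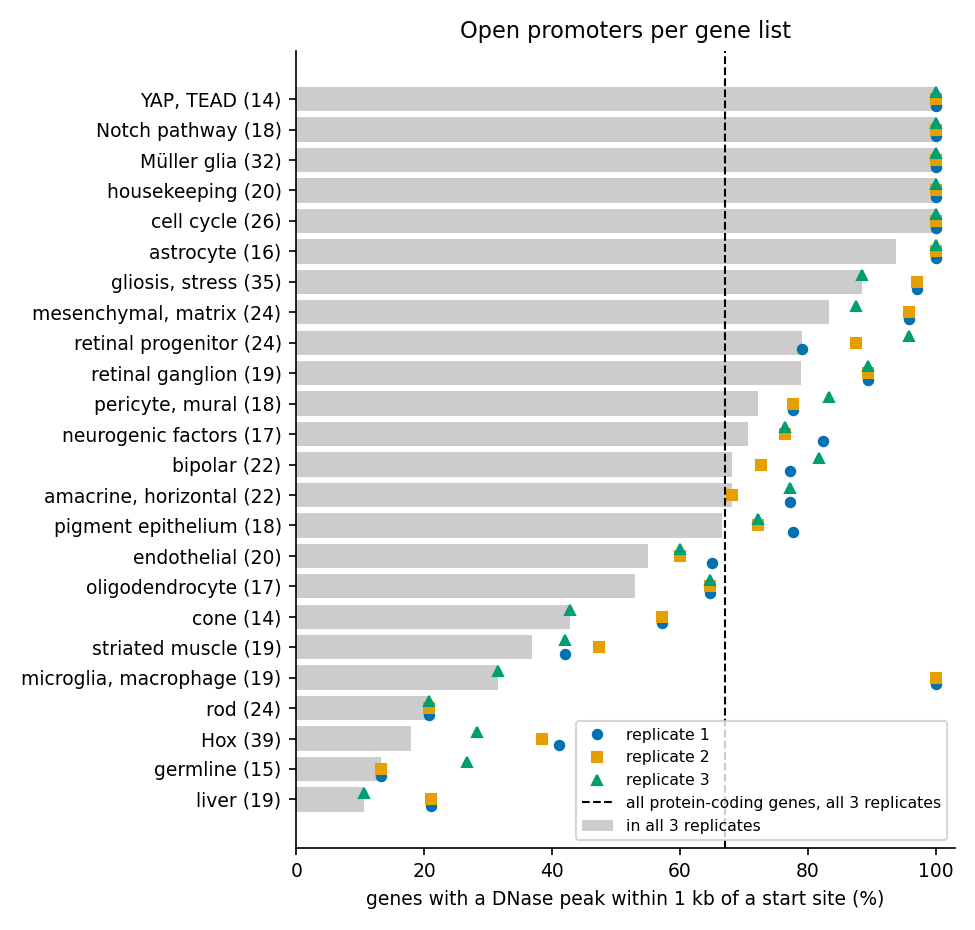
Share of each list's genes with a DNase peak within 1 kb of a start site (x axis, percent), with the number of genes in brackets. Bars stand for reproducible sites, symbols for the peaks of each replicate, and the dashed line for all protein-coding genes (67.1%). Microglia and macrophage genes stand at 100% in replicates 1 and 2 and at 31.6% in replicate 3.

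Microglia and macrophage genes were the list on which the replicates differed most. All 19 genes had a promoter peak in replicate 1 and in replicate 2, and 6 had one in replicate 3. The share was 77.2% ± 39.5 (SD, n = 3), compared with 71.4% ± 1.53 for all genes. By reproducible sites the list was less open than other genes (6 of 19, 31.6%, Fisher's exact test, adjusted p = 0.0057), and without replicate 3 the direction turned, with 19 of 19 open (adjusted p = 0.00527). Irf8, a transcription factor of myeloid cells, had promoter peaks of 118, 117 and 115 in replicates 1, 2 and 3, and Ly86, a surface protein of B cells and myeloid cells, peaks of 51, 56 and 13. Chosen after their values were seen, Spi1, which encodes PU.1, the master factor of the myeloid lineage, had peaks of 101 and 92 in replicates 1 and 2 and none in replicate 3. Cx3cr1, the fractalkine receptor of microglia, had peaks of 83 and 80 and none in replicate 3, and C1qb, a complement gene, had 100 and 100 and none in replicate 3. Against random lists matched on promoter CpG the reproducible sites of the list did not stand apart (permutation test, adjusted p = 0.783).

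**Figure D3:**
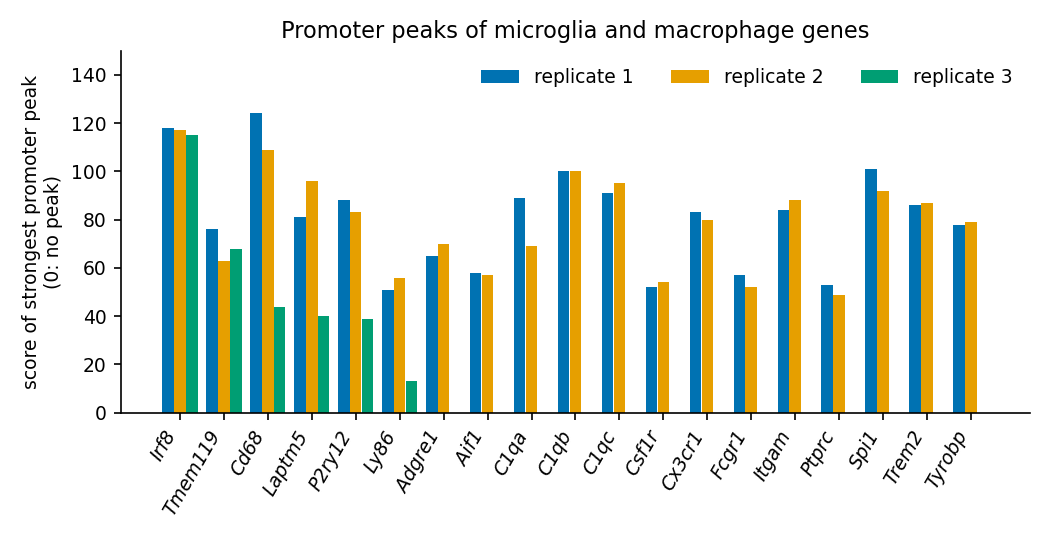
Score of the strongest promoter peak (y axis, deposited score, 0 where no peak was found) of each of the 19 microglia and macrophage genes (x axis) in replicates 1, 2 and 3. A total of 13 genes have bars in replicates 1 and 2 and none in replicate 3.

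Other glial, vascular and connective tissue lists gave mixed results. For astrocyte genes 15 of 16 promoters were open (93.8%), short of the threshold (Fisher's exact test, adjusted p = 0.0542); without replicate 2 or without replicate 3 all 16 were open and the call passed (adjusted p = 0.00571 and 0.0111). Gfap, the intermediate filament of astrocytes and of reactive Müller cells, was open, and its reproducible promoter site at chromosome 11, 102897956 to 102898145 (mm10), lay at a start site inside the gene and scored 61, 41 and 41. Its strongest promoter peaks, 79, 68 and 70, did not all overlap. Slc1a2, a glial glutamate transporter, was open with peaks of 120, 121 and 76. Oligodendrocyte genes were open in 9 of 17 cases (52.9%, exact test, adjusted p = 0.400), endothelial genes in 11 of 20 (55%, adjusted p = 0.367), and pericyte and mural genes in 13 of 18 (72.2%, adjusted p = 0.965). Mbp, Kdr and Foxc1 were open, and Mag, Emcn and Des, markers of myelin, endothelium and muscle cells of vessels, had no promoter peak. Mesenchymal and matrix genes were open in 20 of 24 cases (83.3%, exact test, adjusted p = 0.202), among them Runx1 and Col5a1. In replicates 1 and 2 alone 23 of 24 had a promoter peak and the list passed the exact test (adjusted p = 0.0177 and 0.0122).

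Gliosis and stress genes were open more often than other genes, in 31 of 35 cases (88.6%, Fisher's exact test, adjusted p = 0.0146), and also relative to random lists with the same promoter CpG (24.2 open genes on average, adjusted p = 0.016). Fos, an immediate early gene of the AP-1 family, had promoter peaks of 145, 142 and 139, and Lif, a cytokine of the injury response, of 123, 120 and 86. Edn2, a peptide that injured photoreceptors release, had none. With a promoter window of 500 bp the list fell short of the threshold (82.9% open, exact test, adjusted p = 0.0588).

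Pathway and control lists were fully open or mostly closed. Promoters were open for all 18 Notch pathway genes (adjusted p = 0.00448), all 14 genes of the YAP and TEAD pathway (adjusted p = 0.0161), all 26 cell cycle genes (adjusted p = 0.000252) and all 20 housekeeping genes (adjusted p = 0.00165), by Fisher's exact test. The open genes included Rbpj, the nuclear effector of Notch, Tead1, Mki67 and Actb. At the other end stood Hox genes (7 of 39, 17.9%, exact test, adjusted p = 8.63e-09), liver genes (2 of 19, 10.5%, adjusted p = 5.99e-06), germline genes (2 of 15, 13.3%, adjusted p = 0.000128) and striated muscle genes (7 of 19, 36.8%, adjusted p = 0.0237). Without replicate 3 the shares were 33.3% for Hox and 21.1% for liver genes. Alb, Acta1, Acr and Hoxa11 had no promoter peak in any replicate. Every promoter site of Aurka (cell cycle), Actn3 (striated muscle) and Pecam1 (endothelium) lay nearer to the start site of another gene. These genes were named after their values were seen. In random lists matched on promoter CpG the calls for Müller glia, gliosis, rod, germline and Hox genes held. By the same permutation test those for the Notch pathway (adjusted p = 0.110), YAP and TEAD (0.0734), the cell cycle (0.526), housekeeping (0.109), liver (0.0512) and striated muscle (0.443) did not. Astrocyte genes passed it (10.9 open genes in random lists, adjusted p = 0.0454 by permutation).

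Distal sites gathered near genes of Müller glia and of a few signalling programmes. Of the reproducible sites 86138 were distal and within 100 kb of the nearest start site, a mean of 3.98 per gene. Müller glia genes had 14.0 distal sites per gene, 2.74 times the mean of matched random lists (permutation test, adjusted p = 0.00024), and 29 of the 32 exceeded the median of genes with a like length. The ratio over the replicates' own peaks was 2.62 ± 0.329 (SD, n = 3). By the same permutation test YAP and TEAD genes had 11 sites per gene (ratio 2.47, adjusted p = 0.00192), gliosis and stress genes 10.3 (2.15, adjusted p = 0.00024), Notch genes 10.3 (1.94, adjusted p = 0.0133), retinal progenitor genes 12.2 (1.94, adjusted p = 0.00192) and mesenchymal and matrix genes 12.2 (1.60, adjusted p = 0.02). The lowest p that this permutation test could give was 2e-05 before adjustment, reached by the Müller glia list and the gliosis and stress list. For retinal progenitor genes the permutation call was lost with hotspots (ratio 1.51, adjusted p = 0.0668) and with medians (ratio 1.53, adjusted p = 0.272).

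No other list passed the test of distal sites. The ratios were 1.44 for astrocyte genes (permutation test, adjusted p = 0.262), 1.37 for the cell cycle, 1.34 for housekeeping, 1.24 for oligodendrocytes, 1.2 for endothelium, 1.15 for neurogenic factors, 1.13 for cones, 1.11 for pigment epithelium, 1.01 for rods, 0.986 for microglia and macrophages, 0.979 for pericytes and mural cells and 0.968 for striated muscle. Amacrine and horizontal cell genes had a ratio of 0.915, bipolar genes 0.853, retinal ganglion cell genes 0.744, liver genes 0.743, germline genes 0.645 and Hox genes 0.610. The adjusted p of Hox genes was 0.262 and those of the rest between 0.407 and 1.

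**Figure D4:**
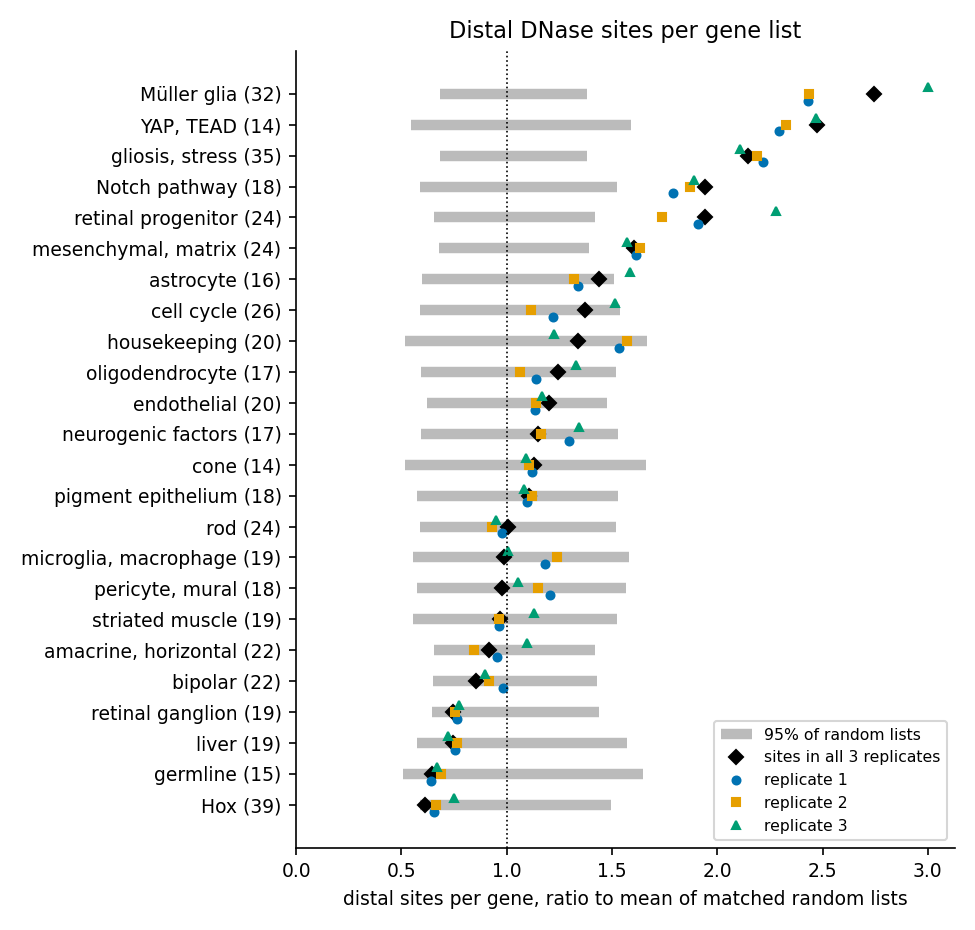
Distal sites per gene of each list as a ratio to matched random lists (x axis), with the number of genes in brackets. Diamonds stand for reproducible sites, the other symbols for each replicate's own peaks, and grey bars for the middle 95% of random lists. Müller glia genes lie highest, at 2.74.

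At single loci, Nfib and Nfia, transcription factors of gliogenesis, had 47 and 34 reproducible distal sites, and Sox2, which keeps neural stem cells and glia undifferentiated, had 45. The replicates' own peaks gave 77 ± 9.54 distal sites at Nfib, 72.7 ± 8.50 at Sox2 and 51 ± 12.2 at Nfia (SD, n = 3). Pax6 had 32, Hes1 28 and Sox9 16. Fos had 31 distal sites and Tead1 43. Nrl had 1 and Crx 1, and the replicates' own peaks gave 2.33 ± 0.577 at Nrl and 1.33 ± 0.577 at Crx (SD, n = 3). Per 100 kb of genome given to each gene, reproducible distal sites numbered 8.51 at Nrl, 4.84 at Crx, 8.08 at Sox9 and 12.8 at Nfib. The counts in this paragraph are not scaled to that length, which was 11745 bp at Nrl and 198000 bp at Sox9. In the genome as a whole the most were found at Pde4d, which encodes a cyclic AMP phosphodiesterase, with 96 sites (177 ± 60 in the replicates' own peaks), followed by Ank3 with 73 and Tenm4 with 59.

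The 10 strongest reproducible distal sites ranked among the first 436 of all reproducible sites in every replicate. They included an intronic site at chromosome 11, 74832136 to 74832325 (mm10), 1216 bp from the start of Mnt, a transcription factor of the MAX network, with scores of 147, 148 and 147. A site between genes on chromosome 12, 85472076 to 85472245, lay 1645 bp from the start of Fos and scored 148, 145 and 145. Another on chromosome 15, 85634536 to 85634765, lay 52063 bp from the start of Wnt7b, which encodes a Wnt ligand, and scored 147, 146 and 146.

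Motifs of CTCF, AP-1, NFI and TEAD factors were among those more frequent in distal sites than in sequence nearby. The AP-1 consensus, bound by Fos and Jun proteins, occurred in 16.8% of the 120288 reproducible distal sites and in 2.10% of windows 1 kb away, a ratio of 7.96. In the replicates' own distal peaks the ratio was 7.11 ± 0.481 (SD, n = 3). CTCF, the architectural factor of chromatin loops, had a site in 3.73% against 0.0386% of windows (ratio 65.8 ± 7.62 over replicates, SD, n = 3). TEAD, through which YAP acts, was found in 7.75% against 2.18% (3.17 ± 0.0924), and the palindromic NFI motif, of the gliogenic factors above, in 0.0898% against 0.00734% (11.8 ± 0.522). SOX motifs were common in sites and windows alike, at 27.7% and 20.4% (1.3 ± 0.00214). By Fisher's exact test 22 of the 28 motifs were more frequent in the sites, 4 less frequent and 2 passed no threshold at an adjusted 0.05.

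Further motifs above their windows were CREB (ratio 5.19 in reproducible sites), CEBP (5.24), RFX (4.01), SP and KLF (2.93), NRF1 (2.23), STAT (2.17), RBPJ of the Notch pathway (2.13), the E-box CAGCTG (2.13), MITF (2.11), RUNX (2.02), ETS (1.88), NFY (1.80), MEF2 (1.67), the homeobox core TAATTA (1.45), PU.1 (1.44), the E-box CAGATG (1.25) and SRF (1.24). Less frequent were GATA (0.472), the E-box CAGGTG (0.663), the OTX and CRX motif of photoreceptors (0.673) and FOX (0.884). HNF4 of liver (1.12, adjusted p = 0.173) and the SOX palindrome (1 site, adjusted p = 0.432) passed no threshold by the exact test. The PU.1 ratio in the replicates' own peaks was 2.25 and 2.36 in replicates 1 and 2 and 1.38 in replicate 3. Sites were richer in G and C than their windows (48.8% against 43.7%). With windows matched on GC content the ratio moved to 3.28 for CREB, 1.48 for SP and KLF, 2.68 for the homeobox core and 2.99 for MEF2, and NRF1 lost its call (1.4, exact test, adjusted p = 0.282), while FOX turned to 1.11; these ratios cover 113945 sites that could be matched. Without replicate 3 the ratio to windows 1 kb away was 2.32 for PU.1 and 1.89 for SP and KLF. Against shuffled versions of each consensus 13 of the 22 stayed above the range, AP-1, CTCF, TEAD and SOX among them, while NFI did not (2.33 times the mean of its shuffled versions).

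**Figure D5:**
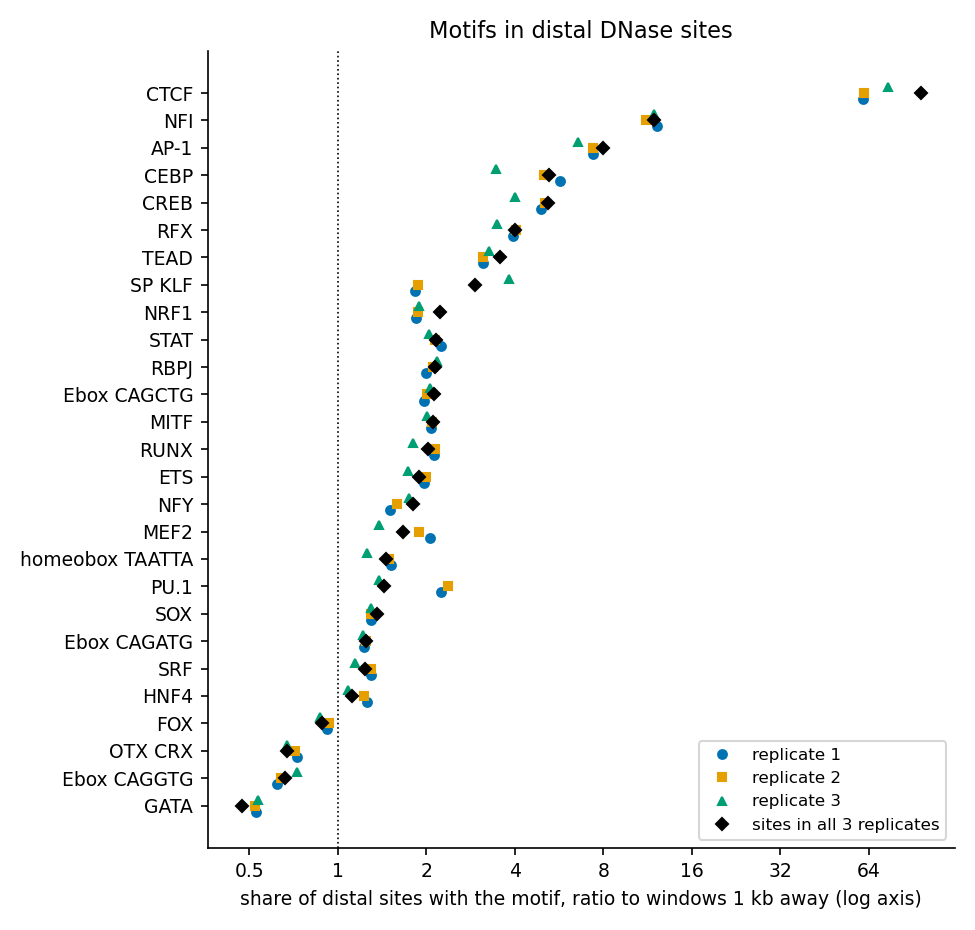
Share of distal sites with each motif as a ratio to windows 1 kb away (x axis, log scale), for reproducible sites (diamonds) and for each replicate's own peaks (other symbols). The SOX palindrome, found in 1 site, is left out. CTCF lies farthest to the right and GATA (0.472) farthest to the left.

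Promoter sites held the motifs of general promoter factors. SP and KLF motifs occurred in 19% of the 24974 reproducible promoter sites and 1.52% of windows (ratio 9.88 ± 1.12 over the replicates' own peaks, SD, n = 3). NFY was found in 4.04% against 0.352% (8.72 ± 0.365), ETS in 3.47% against 0.195% (13.4 ± 0.967), CREB in 1.81% against 0.0867% (18.4 ± 1.03) and NRF1 in 0.857% against 0.0135% (52.8 ± 21.6). AP-1 stood at 4.58% against 1.82% (2.60 ± 0.616) and TEAD at 2.73% against 1.93% (1.43 ± 0.183), ratios below those of distal sites. By Fisher's exact test 15 motifs were more frequent and 10 less frequent. Promoter sites held 63.2% G and C and their windows 46.4%, and only 11207 sites could be matched to windows on GC content. In those sites, a subset, the ratio was 2.51 for SP and KLF (12.5 in all sites), 17.3 for NRF1 (57.6), 11.1 for CREB (20.6), 10.3 for ETS (17.7), 4.49 for AP-1 (2.52) and 2.24 for TEAD (1.42). With the same windows SOX, the homeobox core, RUNX, SRF and MEF2 turned from less to more frequent (ratios 1.24, 2.00, 1.26, 1.64 and 1.93), RBPJ lost its call (1.35, exact test, adjusted p = 0.193), and 19 motifs were more and 4 less frequent.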

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

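Most single results were unchanged under the alternatives, and the cause of the changes below was not tested. The counts that follow include lists and motifs with no call to lose. Among promoter lists calls ended most often with random lists matched on promoter CpG, and among distal motifs with shuffled consensus sequences. For single lists 261 of 288 promoter results and 310 of 312 distal results were unchanged, and for single motifs 207 of 224 in distal sites and 182 of 196 in promoter sites. With the strongest 50% of peaks the mean was 127666 peaks per replicate, and 28.6% of cone and 30% of endothelial promoters were open, both then past the threshold. With hotspots rho was 0.735 (replicates 1 and 2), 0.433 (1 and 3) and 0.462 (2 and 3), with 51.4%, 48.2% and 43.9% of hotspots of replicates 1, 2 and 3 at the capped value, so that ranks are largely tied. With hotspots, too, mesenchymal promoters passed at 91.7% open, and the distal ratio of progenitor genes was 1.51; with medians it was 1.53.

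Random lists matched on promoter CpG left 3 lists higher and 3 lower. Calls then ended for the Notch, YAP and TEAD, cell cycle and housekeeping lists (100% open each), liver (10.5%), striated muscle (36.8%) and microglia and macrophages (31.6%), while astrocyte genes (93.8%) passed. A 500 bp window ended the call of gliosis genes (82.9%). In sites of at least 2 replicates 100% of astrocyte and of microglia and macrophage promoters were open, as in replicate 1 alone and in replicate 2 alone, and for astrocyte genes in replicate 3 alone too. Replicate 1 alone and replicate 2 alone each gave 95.8% for mesenchymal genes, replicate 3 alone 95.8% for progenitor genes, and replicate 2 alone 47.4% for striated muscle, where the call ended.

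Leaving out 1 replicate gave 93.8% to 100% for astrocyte genes, 31.6% to 100% for microglia and macrophages (100% without replicate 3, with the direction turned) and 83.3% to 91.7% for mesenchymal genes. Without replicate 3 the ratio of CEBP in promoter sites was 9.25 (14.3 with all). That of NFI was 3.12 (1.15 with all), then just past the threshold (Fisher's exact test, adjusted p = 0.0495). With all replicates NFI was found in 3 of 24974 promoter sites and 4 of 36915 windows, so its ratio rests on very few matches. Over all alternatives the adjusted p (exact or permutation) ran from 0.00571 to 0.394 for astrocyte, 0.000241 to 0.783 for microglia and macrophage, 0.0122 to 0.525 for mesenchymal, 0.00737 to 0.777 for progenitor and 0.000479 to 0.0588 for gliosis promoters, and from 0.00016 to 0.272 for distal sites of progenitor genes.

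Against shuffled consensus sequences 13 motifs stayed higher and 0 lower in distal sites, and NFY (0.802), SRF (0.471) and CEBP (0.654) lay below 1. That ratio sets a consensus against its shuffled versions in the same sites and uses no windows. A value below 1 is therefore no reversal of the ratio to windows. The ratios to GC-matched windows were 1.58 for NFY, 1.41 for SRF and 3.88 for CEBP. With GC-matched windows FOX turned to 1.11 in distal sites and NRF1 lost its call (1.4). In promoter sites 4 motifs stayed lower, and SOX (1.24), the homeobox core (2.00), RUNX (1.26), SRF (1.64) and MEF2 (1.93) turned above 1. FOX (1.23) also lay above 1 but passed no threshold (exact test, adjusted p = 0.0866).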

Other observations

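Distal sites shared by replicates 1 and 2 without replicate 3, and those in replicate 3 alone, held different motifs when the same number of peaks was taken from each. All tests on such sites, and the genes named in this paragraph, were chosen after the data were seen. AP-1 occurred in 16.7% of the 34602 sites of replicates 1 and 2 and 8% of the 35129 sites of replicate 3, RUNX in 8.67% and 4.49%, and SP and KLF motifs in 0.468% and 2.95%. TEAD stood at 5.56% and 5.74% (Fisher's exact test, adjusted p = 0.329). These sets are not alike in kind, since the first needed a peak in 2 replicates and the second in 1. Their median strength lay at percentiles 30.7 and 31.3 of the peaks taken from replicates 1 and 2, and 16.6 in replicate 3. The motif differences therefore cannot be told apart from differences in strength or replication. These sets were also not matched on GC content. Such matching moved the SP and KLF ratio in reproducible distal sites from 2.93 to 1.48. AP-1 occurred in 14.6% of distal sites of replicate 1 alone and 15.1% of those of replicate 2 alone. The genes with most sites of replicates 1 and 2 alone were Nav2 (42), Arid5b (38) and Pde4d (37). Those with most sites of replicate 3 alone were Barx1 (24), Sox2 (24) and Otx1 (23). These counts were not scaled to the length of genome given to each gene. Pde4d, Nav2 and Sox2 were also rich in reproducible distal sites (96, 54 and 45), so their rank need not mark a difference between replicates. No theme of these genes was tested. At promoters, with the same number of peaks, 4 progenitor and 4 bipolar genes had a peak in replicate 3 alone, short of the threshold (exact test, adjusted p = 0.083 for each), and with all peaks 2 progenitor genes (Lin28a and Sfrp2) and 0 bipolar genes did.

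Of the tests on microglia and macrophage promoters, the one with equal peak numbers was chosen after its result was seen. Of 19 genes 13 kept peaks in replicates 1 and 2 and none in replicate 3 at equal peak numbers. This argues against fewer peaks as the whole cause. CpG-matched random lists had 0.583 such genes on average (permutation p = 2e-05, the smallest it can give). The 13 genes had been seen before, and genome-wide 308 of 21646 genes (1.42%) had the pattern. Matched lists were therefore bound to hold few such genes, so that p restates the observation and is no independent support. These values show only that the pattern was rare among genes of like promoter CpG. T cell, B cell and erythroid genes had the pattern in 5.88% of cases (2 of 14 T cell, 0 of 10 B cell and 0 of 10 erythroid genes, exact 95% interval 0.720 to 19.7), which argues against blood cells of all lineages. A second macrophage list, with no gene of the first, had it in 52.4% (11 of 21, interval 29.8 to 74.3), so a hypothesis is that replicates 1 and 2 may hold cells of the macrophage lineage that replicate 3 holds less of. With all peaks, 6 of 19 genes of the first list and 7 of 21 of the second had a promoter peak in replicate 3. Among them Irf8, Tmem119 and Sall1, chosen after their values were seen, had peaks in all 3 replicates. The labels name no sort that would remove such cells. The design, with a single group, names no biological difference between replicates that could be tested.

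The same question was put to every list and replicate. With the same number of peaks, promoters missing in just 1 replicate numbered 118, 156 and 308 genome-wide for replicates 1, 2 and 3, and 0, 0 and 13 in the microglia and macrophage list, the sole list past the threshold in 72 exact tests (adjusted p = 1.38e-18). The 13 genes had been seen before these tests were set up, so that p restates the observation and is no independent support. It is over genes and does not measure the spread between replicates. With all peaks 653 genes had a promoter peak in replicates 1 and 2 and none in replicate 3. The median promoter score of that list was 83, 80 and 0 in replicates 1, 2 and 3, that of the second macrophage list 72, 54 and 0, and that of housekeeping genes 137, 134 and 124.

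The PU.1 motif, of the myeloid factor Spi1, was tested in distal sites after its ratios in each replicate had been seen, so these values restate that observation and are no independent support. In sites of replicates 1 and 2 alone it was 4.67 times as frequent as in windows 1 kb away, and in those of replicate 3 alone 1.24 times. Sites of replicate 1 alone had 2.23, and of replicate 2 alone 3.74; the ratio was 1.11 for replicates 1 and 3, 1.21 for replicates 2 and 3, and 1.48 for sites in all 3. Cells of the macrophage lineage in replicates 1 and 2 may give such values, as a hypothesis, but the consensus overlaps those of other ETS factors and shows no binding. The design names no other difference between these replicates to test.

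For distal sites in replicate 3 alone, the AP-1 test was chosen after its result was seen. At equal peak numbers AP-1 was 3.73 times as frequent as in their windows. This argues against background without regulatory sequence as the whole source of that set. The smaller set in replicate 3 alone with all peaks was not tested for AP-1. Their median strength lay at percentile 16.6 of that replicate's peaks (score 22, against a median of 42), so many may be weak peaks near the calling threshold. With all peaks of replicates 1 and 2 the regions of replicate 3 alone fell from 41667 to 20023 in number, so many are weaker peaks of the other replicates; depth is unknown, and no biological explanation of these sites was tested.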
